A study of Mus musculus with 9 samples.

How the data were processed

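RNA from 9 mouse organoid libraries was sequenced: 3 of normal lung organoids (Normal), 3 of small cell lung cancer organoids (SCLC) and 3 of SCLC organoids treated with GSK. Per the labels, libraries were made with a stranded mRNA kit (NEB E7770), sequenced on an Illumina NovaSeq sequencer as paired reads of 150 bp, and aligned with STAR 2.7.9a to GRCm39. The counting tool, the tool for differential expression and the annotation release are not given in the sources used here. What GSK is, its dose and the time of treatment are not given there either.

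The deposited files used were a pair of comparison tables of 57010 Ensembl gene identifiers each, SCLC against Normal and GSK against control, with 3 libraries against 3. Their column names and their rules for missing values are those of a DESeq2 results table, per the file headers. The signal column, in which the authors gave each gene's mean over the 6 libraries of a comparison, holds normalized counts. The authors' log2 fold change and its standard error came from their fit and showed no shrinkage. The score column held the authors' statistic, which equalled the fold change divided by its standard error to within 8.9e-08. The p-value columns held the authors' unadjusted p-value and their adjusted p-value, which matched a two-sided normal p-value and a Benjamini-Hochberg adjustment over the genes with an adjusted value when recomputed, to within 0.004 on the log10 scale. No column held a single library, so depths per library, replicate spread, principal components and pairing of replicate numbers were not analysed here.

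The first table gave an adjusted p for 24719 genes and the second for 28376. A further 8801 and 7412 genes had a p-value without an adjusted one, and 134 and 108 had a fold change without a p-value. The control of the second table is not tied to samples by its name, so group means were implied from each mean and fold change, with 3 libraries per group. Over 13634 genes with a mean of at least 50 in both tables, the log2 ratio of the implied control mean to the implied SCLC mean of the first table had a median of 0.109 and an SD of 0.0084, against an SD of 2.02 if the other arm had been the SCLC group. The control was therefore taken as the SCLC group. The tables were scaled separately, and no p-value was computed for a difference between groups of different tables. Values were set across them for the match of the SCLC means, for opposite change and for the level of Xist in Normal and GSK.

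Because no library values were used, the test was the one fixed for that case before the data were examined: the authors' adjusted p under 0.05. A floor of 3 normalized counts per group, a mean of 1, was used for fold changes: where one group lay under it, the fold was computed against the floor and given as a lower bound. The bound concerns the group under the floor only. The other group entered with its implied mean and without its error, so the bound is not a confidence limit. Implied totals and floors cover counting error only. Of the identifiers, 33116 had a symbol in the table, 19973 were named through the reference annotation (GENCODE M21, build GRCm38), which also gave gene biotype, transcript length and GC content, and 3921 had no symbol. No coordinates were used, since the builds differ.

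The 37 gene lists were fixed before the data were examined and held 603 genes, of which 1 had no entry. For each list, members with an adjusted p were counted as higher, lower or not passing, and the counts were repeated with p-values adjusted over the list alone. The list test was cameraPR of limma 3.58.1 in R 4.3.3 on the authors' statistic, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 37 lists of a comparison. It asks whether the mean statistic of the members differs from that of other genes. An estimated correlation and fry need library values and were not run, so each call lost at a preset correlation of 0.1 is given beside its list. Members without an adjusted p in SCLC against Normal included Stmn2, Dcx, Ankrd1, Pou2f3, Gfi1b, Il25, Rgs13, Lypd2, Krt5, Krt14, Krt15, Col17a1, Cd3e, Cd3d, Nkg7, Esrp1, Khdrbs2, Ifit1, Mx2, Rsad2, Cxcl5, Cxcl10, Pdcd1lg2 and Ido1. In GSK against SCLC they were Dcx, Yap1, Pou2f3, Il25, Rgs13, Slc34a2, Trp63, H60c and Pmaip1.

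Named genes followed a rule fixed at the same time. It took the 10 largest rises and falls among genes that passed, had an official symbol and were among the 5000 highest means. It also took up to 4 members per list with the largest change among those that passed, and 23 genes named in advance. The rule asked for the mean of the higher group, but the mean over the 6 libraries of a comparison was used. The part of the rule that asked for groups without overlap needs library values and was not applied. Where a list had 5 or fewer members that changed one way, all were named, and those outside the rule were chosen after their values were seen. Xist and the Y-linked genes were chosen in the same way. Some genes that these rules select are not reported here.

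Opposite change was counted over the 23797 genes tested in both tables. Because the SCLC libraries serve in both, 100 draws of groups with no true change were simulated against shared SCLC errors taken from the authors' standard errors (seed 1), with 0.5 of the smaller squared error counted as the part of the SCLC libraries. The calling step was tested on simulated data with 200 genes changed, far fewer than were called in either table, so that its p-value cut was stricter than theirs and its recovery is not that of the calls reported. In SCLC against Normal, over 24719 genes, 16.0% of changes of 1 log2 unit and 42.0% of changes of 2 were recovered, and 3.3% of calls were false. In GSK against SCLC, over 28376 genes, these were 14.0%, 40.0% and 11.5%. The false shares came from a single draw per comparison, with 2 and 7 unchanged genes called. They are not the false shares of the calls reported and do not rank the comparisons.

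Alternatives fixed in advance that the tables allowed were scaling to implied total counts, no filter on low means, an added threshold of 1 on the absolute log2 fold change, and leaving out mitochondrially encoded and ribosomal protein genes. Chosen after seeing the data were centring on genes with a mean of at least 100, a minimum mean of 10, a Wald test of changes above 1, a preset correlation of 0.1, ranks of the statistic, opposite change without markers of other cell types and after scaling to total counts, and removal of trends with transcript length and GC content. Scaling to total counts shifted log2 fold changes by 0.09 in SCLC against Normal and by 0.51 in GSK against SCLC. For trend removal, the median fold change in 20 bins of length and of GC content, over protein-coding genes outside the core spliceosome, ribosomal protein and cholesterol lists with an SCLC mean of at least 100, was subtracted, for the 96.3% and 95.4% of tested genes with an annotated transcript, and the longest transcript stood for its gene. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.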

Results

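RNA was sequenced from mouse organoids, which are cell cultures that grow into small tissue-like bodies. The 9 libraries formed 3 groups of 3: normal lung organoids (Normal), small cell lung cancer organoids (SCLC), and SCLC organoids treated with a compound named GSK in the labels (GSK). The values were the authors' own comparisons of 3 libraries against 3, with a fold change for each gene and no value for a single library, so the spread between replicates was seen only through the authors' standard errors. The mean of the summed normalized counts per library was 43.4 M counts (M, mega) in the authors' deposited table of SCLC against Normal and 38.6 M in the authors' deposited table of GSK against SCLC. The sums implied for each group were 44.7 M for Normal, 42.0 M for SCLC in the first table, 45.3 M for SCLC in the second table and 31.9 M for GSK, from the authors' deposited tables. Fold changes are given on the log2 scale ± the authors' standard error, and "at least N-fold" marks genes whose lower group lay under a mean of 1 normalized count. Such a value takes the mean of the higher group without its error, so it is not a confidence limit. Levels are group means implied by the authors' mean and fold change.

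The comparison of SCLC with Normal asked how transcript levels of the tumour organoids differed from those of normal lung organoids. The neuroendocrine transcription factor Insm1 was at least 62100-fold higher in SCLC in the authors' deposited table (adjusted p = 1.42e-39). Chga, a protein of neuroendocrine secretory granules, rose by 13.82 ± 1.08 (adjusted p = 5.07e-36) in the authors' deposited table. Myc, a driver of cell growth, rose by 6.98 ± 0.39 (adjusted p = 1.31e-70), in the authors' deposited table. Genes of the lung epithelium fell: the surfactant gene Sftpc had a log2 fold change of -13.10 ± 0.26 (adjusted p listed at 0) and the club cell secretory protein gene Scgb1a1 of -12.95 ± 0.62 (adjusted p = 8.45e-95), in the authors' deposited table. Of 24719 genes tested, 12453 changed in the authors' deposited table, 6252 higher and 6201 lower in SCLC, which was 50.4% of those tested.

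Among the 10 largest rises of abundant genes were Eef1a2, Insm1, Crmp1, Chga, Gdap1l1, Scg3, Gpr37l1 and Kcnc1 in the authors' deposited table. Eef1a2, an elongation factor of neurons and muscle, was at least 37800-fold higher, and Crmp1, which acts in axon guidance, was at least 10300-fold higher, in the authors' deposited table. The 10 largest falls were those of Lyz1, Clic5, Slc6a14, Ereg, Il18r1, Gja1, Lyz2, Chil1, Serpinb6b and Cldn18 in the authors' deposited table. Lyz1, a lysozyme, was at least 19500-fold lower, and Clic5, a chloride channel protein of alveolar type I cells, had a log2 fold change of -16.47 ± 0.65 (adjusted p = 6.32e-140), in the authors' deposited table. The Normal libraries had a mean of 31710 for Xist, the RNA of the inactive X chromosome, against 1.76 in SCLC, in the authors' deposited table. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were at least 1010-fold, 532-fold, 1110-fold and 370-fold higher in SCLC, in the authors' deposited table. Groups thus differed in sex-linked transcripts as well as in tumour status. These 5 genes were chosen after their values were seen.

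Of 20 neuroendocrine markers tested, 19 rose and 1 fell in the authors' deposited table (list test adjusted p = 5.14e-26). Scg3, a granin, was at least 5720-fold higher, Neurod1, a neurogenic transcription factor, was at least 14.6-fold higher (adjusted p = 0.0185), and Nkx2-1, a lung lineage factor, fell (-0.91 ± 0.32, adjusted p = 0.011) in the authors' deposited table. Of 16 neuronal and synaptic genes, 15 rose in the authors' deposited table (list test adjusted p = 1.12e-13), among them Stmn3, a regulator of microtubules (12.26 ± 0.90), and Syt4, a synaptotagmin (at least 928-fold). All 16 tested genes of the non-neuroendocrine SCLC list fell in the authors' deposited table (list test adjusted p = 2.32e-15), with Wwtr1, a Hippo pathway coactivator, at -9.47 ± 0.47 and Lgals3, a galectin, at -9.37 ± 0.29. Among 6 tuft cell markers, Ascl2 (-4.81 ± 0.90) and Alox5ap (-2.25 ± 0.90) fell in the authors' deposited table. The tuft cell list did not pass (list test adjusted p = 0.702).

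All 15 alveolar type II markers fell in the authors' deposited table (list test adjusted p = 5.59e-48). Lyz2, a lysozyme, had a log2 fold change of -15.42 ± 0.48, and Lamp3, a lamellar body protein, of -13.42 ± 0.41, in the authors' deposited table. Of 13 alveolar type I markers, 11 fell and Igfbp2 (3.25 ± 0.81) and Spock2 (3.59 ± 0.31) rose in the authors' deposited table (list test adjusted p = 5.29e-25). Ager, the receptor for glycation products, had -11.92 ± 0.40 in the authors' deposited table. Of 13 club and secretory cell markers, 11 fell in the authors' deposited table (list test adjusted p = 7.92e-09), with Cbr2, a carbonyl reductase, at -10.90 ± 0.48 and Scgb3a2, a secretoglobin, at least 643-fold lower. Of 13 ciliated cell markers, 8 fell and Mlf1 rose (3.62 ± 0.76) in the authors' deposited table, and Cfap52, a protein of the axoneme, had -7.11 ± 0.70. The ciliated cell list did not pass (list test adjusted p = 0.0568). Among 6 basal cell markers, Trp63 (at least 178-fold), Krt17 (at least 360-fold), Dapl1, Aqp3 and Snai2 fell in the authors' deposited table (list test adjusted p = 0.0411; 0.102 with a preset correlation of 0.1).

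Of the markers of cells outside the epithelium, the fibroblast and immune lists were lower in SCLC as well, while the endothelial and erythroid lists did not pass. Of 13 fibroblast markers, 11 fell and Thy1 rose (3.87 ± 0.72) in the authors' deposited table (list test adjusted p = 4.35e-05), with the collagen genes Col1a2 at -8.94 ± 0.81 and Col3a1 at -9.96 ± 1.61. Of 10 immune cell markers, 9 fell in the authors' deposited table (list test adjusted p = 0.000163), among them the macrophage gene Adgre1 (at least 735-fold lower) and the myeloid integrin Itgam (at least 254-fold lower). Among 10 endothelial markers, Cdh5, Tie1, Emcn, Tek and Esam fell in the authors' deposited table (Esam, an adhesion molecule, -8.22 ± 0.45). The endothelial list did not pass (list test adjusted p = 0.0807). Among 5 erythroid genes, the globin genes Hba-a1 (at least 13.7-fold) and Hbb-b1 (at least 10.1-fold) fell in the authors' deposited table. The erythroid list did not pass (list test adjusted p = 0.581).

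Most genes of the splicing machinery were higher in SCLC. Of 42 core spliceosome components, 36 rose and 0 fell in the authors' deposited table (list test adjusted p = 4.53e-11). Their median log2 fold change was 1.90, or 1.72 relative to genes with a mean of at least 100, in the authors' deposited table. Sf3a2, of the U2 particle, rose by 3.34 ± 0.26 (adjusted p = 2.39e-37) and Snrpc, of the U1 particle, by 2.86 ± 0.30, in the authors' deposited table. Of 25 hnRNP proteins, which bind nascent RNA, 20 rose (21 adjusted over the list alone) and Ptbp3 fell (-0.89 ± 0.35) in the authors' deposited table (list test adjusted p = 0.000409; 0.0511 with a preset correlation of 0.1). Ptbp1, a repressor of exons, rose by 1.75 ± 0.20 in the authors' deposited table. Of 13 SR proteins, which promote exon use, 8 rose and Srsf5 (-0.78 ± 0.23) and Srsf11 (-0.55 ± 0.22) fell in the authors' deposited table. Srsf7 rose by 1.90 ± 0.27 and Srsf1 by 1.18 ± 0.24 (adjusted p = 2.91e-06) in the authors' deposited table. The SR protein list did not pass (list test adjusted p = 0.0712). Of 24 tissue-restricted splicing regulators, 17 rose and 6 fell in the authors' deposited table (list test adjusted p = 2.16e-05). The neuronal RNA-binding genes Elavl3 (11.66 ± 0.71) and Srrm3 (10.63 ± 0.97) rose, and Elavl4 was at least 741-fold higher, in the authors' deposited table.

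Of 12 protein arginine methyltransferases and their partners, which modify splicing factors among other proteins, 9 rose and Prmt2 (-0.83 ± 0.21) and Prmt8 (at least 33-fold lower) fell in the authors' deposited table (list test adjusted p = 0.00375; 0.0511 with a preset correlation of 0.1). Prmt1 rose by 2.97 ± 0.27 (adjusted p = 1.98e-26), Prmt5 by 1.61 ± 0.31 (adjusted p = 1.13e-06) and Carm1 by 1.95 ± 0.23 (adjusted p = 3.56e-16) in the authors' deposited table. Among 10 splicing factor kinases, Srpk1 (1.70 ± 0.22) and Dyrk1a (0.59 ± 0.21) rose and Clk1 (-1.97 ± 0.27), Clk4, Srpk2 and Prpf4b fell in the authors' deposited table. The kinase list did not pass (list test adjusted p = 0.724). Of 14 nonsense-mediated decay factors, 8 rose and Upf2 fell (-1.16 ± 0.27) in the authors' deposited table, and Magoh, of the exon junction complex, rose by 1.83 ± 0.37. The decay factor list did not pass (list test adjusted p = 0.0712). Of 24 cytosolic ribosomal proteins, 19 rose and 0 fell in the authors' deposited table (list test adjusted p = 0.00123; 0.0667 with a preset correlation of 0.1), with Rplp2 at 1.66 ± 0.36 and Rpl8 at 1.48 ± 0.21. Across genes, which are not independent replicates, fold changes in the authors' deposited table followed GC content of the transcripts (rank correlation 0.15) and their length (-0.10). The median went from -0.02 in the lowest of 20 bins of GC content to 1.29 in the highest, and from 0.75 in the shortest bin of length to 0.20 in the longest, from the authors' deposited table.

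Genes of antigen presentation and innate signalling were mostly lower in SCLC, together with the immune cell markers. Of 22 MHC class I pathway genes, 11 fell and H2-Q6 (3.05 ± 0.76), H2-Q7 (3.63 ± 0.76), Psmb9 (1.17 ± 0.48) and Calr (0.90 ± 0.27) rose in the authors' deposited table. The MHC class I list did not pass (list test adjusted p = 0.224). The light chain gene B2m fell (-2.24 ± 0.47, adjusted p = 6.98e-06), as did H2-D1 (-1.33 ± 0.27, adjusted p = 4.78e-06), the peptide transporter gene Tap1 (-0.94 ± 0.32, adjusted p = 0.00912) and its partner Tapbp (-2.53 ± 0.21), in the authors' deposited table. H2-K1 fell (-0.51 ± 0.21, adjusted p = 0.0297) in the authors' deposited table, a call that ended when fold changes were scaled to total counts (-0.42, adjusted p = 0.0786), and Nlrc5, the transactivator of these genes, had 0.65 ± 0.79 (adjusted p = 0.512). All 8 MHC class II genes fell in the authors' deposited table (list test adjusted p = 6e-08), with Cd74, the invariant chain, at -9.50 ± 0.40 and H2-DMb1 at least 1050-fold lower.

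Of 26 interferon response genes, 21 fell and 0 rose in the authors' deposited table (list test adjusted p = 1.38e-06). Ifit3, an antiviral effector, had -8.77 ± 0.65 in the authors' deposited table. Of 11 nucleic acid sensing genes, 8 fell and Cgas, a DNA sensor, rose (1.60 ± 0.36) in the authors' deposited table (list test adjusted p = 0.000409), and Rigi, an RNA sensor, had -5.55 ± 0.30. Of 19 chemokines and inflammatory cytokines, 18 fell in the authors' deposited table (list test adjusted p = 1.83e-08). Ccl2, a monocyte attractant, had -9.30 ± 0.64, and Cxcl10, a T cell attractant, had -5.56 ± 1.78 with no adjusted p, in the authors' deposited table. Of 14 immune checkpoint ligands and related surface genes, 9 fell and Cd276 (2.59 ± 0.28), Icosl (1.0 ± 0.43) and Cd24a (1.82 ± 0.52) rose in the authors' deposited table. Cd274, which encodes PD-L1, fell (-3.06 ± 0.87, adjusted p = 0.00132) in the authors' deposited table. The checkpoint list did not pass (list test adjusted p = 0.0503). Among 5 NKG2D ligands, which mark stressed cells for killing, Raet1e (-8.24 ± 0.64), H60b and H60c fell and Ulbp1 rose (2.32 ± 0.26) in the authors' deposited table. The NKG2D ligand list did not pass (list test adjusted p = 0.139).

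Genes of cell division rose throughout their lists. All 21 mitotic genes rose in the authors' deposited table (list test adjusted p = 1.12e-13), among them Ube2c, of the anaphase-promoting machinery (4.99 ± 0.39), the cyclin gene Ccnb1 (4.51 ± 0.42) and the proliferation marker Mki67 (2.57 ± 0.36, adjusted p = 3.47e-12). All 22 DNA replication genes rose in the authors' deposited table (list test adjusted p = 6.78e-13), with the origin licensing genes Cdt1 at 3.96 ± 0.28 and Mcm2 at 3.40 ± 0.28. In the list of 14 tumour suppressor and MYC family genes, 6 rose and Rb1 (-2.02 ± 0.24, adjusted p = 5.75e-16) and Rbl2 (-1.01 ± 0.24) fell in the authors' deposited table. This list of 14 did not pass (list test adjusted p = 0.0568). Mycl rose by 2.96 ± 0.52 (adjusted p = 6.71e-08) and Mycn by 2.22 ± 0.80 (adjusted p = 0.0126), and Trp53 had -0.27 ± 0.69 (adjusted p = 0.767), in the authors' deposited table. Of 19 p53 targets, 13 fell and Aen rose (1.01 ± 0.27) in the authors' deposited table (list test adjusted p = 0.00144; 0.0553 with a preset correlation of 0.1). The death receptor gene Tnfrsf10b had -3.46 ± 0.30 and the cell cycle inhibitor gene Cdkn1a had -1.60 ± 0.39 (adjusted p = 0.000115) in the authors' deposited table.

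The remaining lists did not pass the list test. Of 13 BCL2 family genes, 6 fell and Bcl2 (1.42 ± 0.50), Bak1 (0.80 ± 0.34) and Bok (6.42 ± 0.34) rose in the authors' deposited table. In the authors' deposited table the median of this family, -0.33, and its mean, -0.31, were negative while the test pointed up (list test adjusted p = 0.996). Of 15 genes of the unfolded protein and integrated stress response, Asns, Chac1, Sdf2l1, Psat1 and Phgdh (2.94 ± 0.35) rose and Dnajb9 (-1.74 ± 0.23) and Herpud1 fell in the authors' deposited table (list test adjusted p = 0.388). Asns, Psat1 and Phgdh make amino acids. Of 17 cholesterol biosynthesis genes, 8 fell and Dhcr7 rose (1.11 ± 0.20) in the authors' deposited table (list test adjusted p = 0.289), with Lss, a cyclase of the pathway, at -1.59 ± 0.28. Of 15 hypoxia and glycolysis genes, 6 fell and Eno1 (1.37 ± 0.22), Pdk1 (0.65 ± 0.25) and Egln3 (3.46 ± 0.70) rose in the authors' deposited table (list test adjusted p = 0.202); the vessel growth factor gene Vegfa had -4.73 ± 0.36. Of 13 mitochondrially encoded genes, mt-Nd3 rose (1.36 ± 0.45) and mt-Nd5 (-0.79 ± 0.27) and mt-Nd6 (-0.77 ± 0.24) fell in the authors' deposited table (list test adjusted p = 0.849).

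Adjusted over the list alone, 33 of the 37 lists kept the counts given; the others were 16 neuronal genes higher, 1 tuft cell marker lower, 21 hnRNP genes higher and 4 BCL2 family genes higher, from the authors' deposited table. A test of absolute log2 fold changes above 1 left 2949 genes higher and 3391 lower from the authors' deposited table, and the median log2 fold change of genes with a mean of at least 100 was 0.18. From the authors' deposited table, the calls of H2-K1, Srsf11 and Prpf4b ended when scaled to total counts, and those of Srpk2, Srsf11, Ptbp3, Prpf4b, Psmb9 and Bak1 after removal of the length and GC trends. Sex-linked transcripts differed with the groups, so tumour status and sex could not be separated in the authors' deposited table.

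**Figure D1:**
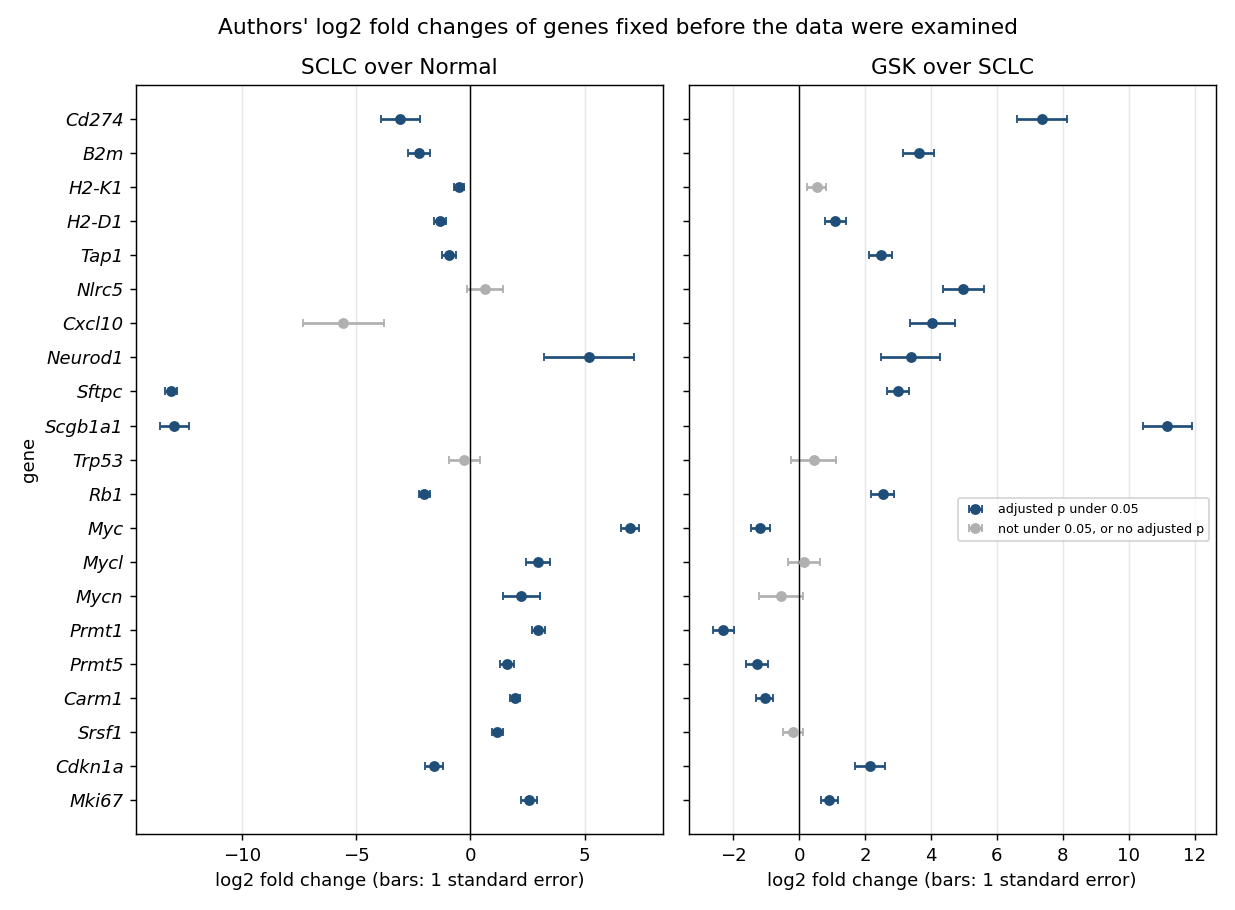
The log2 fold change (horizontal axis) ± 1 SE of genes fixed before the data were examined, from the authors' deposited tables, for SCLC over Normal and for GSK over SCLC; blue marks an adjusted p under 0.05 and grey the others. In the authors' deposited tables Cd274 lies at -3.06 and then at 7.37, and the point of Neurod1 for SCLC over Normal is a fitted value against a group under the floor, not a bound.

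The comparison of GSK with SCLC asked how transcript levels of the treated organoids differed from those of the SCLC organoids. Immune genes that lay under the floor in SCLC were among the largest rises. Chil3, a macrophage lectin, was at least 23700-fold higher, S100a9, a neutrophil protein, at least 13300-fold and Ptprc, the common leukocyte antigen, at least 12600-fold, in the authors' deposited table. Cd274 rose by 7.37 ± 0.76 (adjusted p = 2.87e-20) and B2m by 3.63 ± 0.47 (adjusted p = 3.07e-13), while Insm1 fell (-1.95 ± 0.27, adjusted p = 7.72e-12), in the authors' deposited table. All 14 immune cell markers rose in the same libraries, so the rises of Cd274 and B2m are not tied to the SCLC cells. All 24 cytosolic ribosomal protein genes tested, all 17 cholesterol biosynthesis genes and 25 of 42 core spliceosome components fell in the authors' deposited table. Of 28376 genes tested, 10533 (37.1%) changed in the authors' deposited table, 6129 higher and 4404 lower in GSK, and 2082 of the genes that rose lay under the floor in SCLC.

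The split of calls depended on the scaling. Scaling to total counts added 0.51 to each log2 fold change and gave 8738 genes higher and 1970 lower (81.6% higher, against 58.2% by the authors' scaling), from the authors' deposited table. Centring on genes with a mean of at least 100, whose median was -0.25, gave 7242 higher and 3077 lower (70.2% higher), from the authors' deposited table. Fold changes also followed properties of the transcripts. Among 11116 other protein-coding genes, the median log2 fold change went from -1.11 in the shortest of 20 bins of length to 0.16 in the longest (rank correlation 0.32), from the authors' deposited table. It went from 0.22 in the lowest bin of GC content to -1.12 in the highest (rank correlation -0.34), from the authors' deposited table. Removing both trends, an alternative chosen after seeing the data, gave 6215 genes higher and 3608 lower, from the authors' deposited table.

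The 10 largest rises among abundant genes were Chil3, Ccl6, Ctss, Igha, S100a9, Ptprc, Lilrb4b, Igkc, Csf3r and S100a8, all from under the floor in SCLC, in the authors' deposited table. Igha and Igkc, the constant regions of immunoglobulin A and of the kappa light chain, were at least 14100-fold and at least 8320-fold higher in the authors' deposited table. The 10 largest falls were those of Pcdh10, B3gat1, Scx, Lingo1, Hapln4, Gli3, Tmem238, Nt5dc2, Scd2 and Scd1 in the authors' deposited table. Pcdh10, a protocadherin, had -5.81 ± 0.42 (adjusted p = 2.66e-41), and the fatty acid desaturase genes Scd2 and Scd1 had -3.0 ± 0.35 and -3.0 ± 0.43, in the authors' deposited table. Xist had a mean of 15.7 in GSK, against 1.87 in SCLC (3.06 ± 0.96, adjusted p = 0.00551), in the authors' deposited table.

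Markers of several cell types that were low or absent in SCLC rose in GSK. All 14 immune cell markers rose in the authors' deposited table (list test adjusted p = 8.4e-28). Above the floor lay 4 of the 14 in SCLC and 14 in GSK, where S100a9 reached a mean of 13346, in the authors' deposited table. All 10 endothelial markers rose in the authors' deposited table (list test adjusted p = 9.78e-19), with the vessel genes Cdh5 at least 5310-fold and Tie1 at least 1840-fold higher. Of 13 fibroblast markers, 12 rose and 0 fell in the authors' deposited table (list test adjusted p = 3.85e-19), with Col3a1 at 10.68 ± 0.74 and Postn, a matrix protein, at least 1030-fold higher. The erythroid genes Hba-a1, Hba-a2, Hbb-b1, Hbb-bt and Alas2 all rose in the authors' deposited table (list test adjusted p = 0.000235), with Hbb-b1, an adult globin, at least 2350-fold higher and Alas2, a haem synthesis enzyme, at 2.04 ± 0.75.

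Markers of lung epithelium rose too. Of 14 alveolar type II markers, 9 rose and Lpcat1 fell (-0.73 ± 0.25) in the authors' deposited table (list test adjusted p = 3.63e-07). Lyz2, which macrophages also express, had 15.12 ± 0.60 and Sftpc 3.0 ± 0.33 (adjusted p = 2.13e-18) in the authors' deposited table. Of 13 alveolar type I markers, 10 rose and the water channel gene Aqp5 fell (-4.59 ± 0.63) in the authors' deposited table (list test adjusted p = 5.38e-05), with Clic5 at 10.14 ± 0.76. Of 14 club and secretory cell markers, 9 rose and Aldh1a7 fell (-2.45 ± 0.70) in the authors' deposited table (list test adjusted p = 1.66e-06), and Scgb1a1 rose by 11.16 ± 0.74 (adjusted p = 2.43e-48). All 13 ciliated cell markers rose in the authors' deposited table (list test adjusted p = 1.03e-08), with Cdhr3, a cadherin of ciliated cells, at least 109-fold and Dnali1, a dynein chain, 4.35 ± 0.86 higher. Among 9 basal cell markers, Krt14 (at least 4.91-fold), Krt17 (at least 350-fold), Dapl1 and Aqp3 rose in the authors' deposited table (list test adjusted p = 0.0328; 0.113 with a preset correlation of 0.1, and 0.0705 when scaled to total counts).

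Neuroendocrine genes were lower in part. For scale, the 139 genes under the floor in Normal with an SCLC mean of at least 300 had a median of -0.91 in GSK. The neuroendocrine and neuronal medians were no lower than that. A smaller share of SCLC cells was thus not separated from a change within these cells. Of 20 neuroendocrine markers, 8 fell and Neurod1 (3.38 ± 0.89, adjusted p = 0.000755), Calca (1.15 ± 0.40) and Pcsk1 (1.84 ± 0.56) rose in the authors' deposited table (list test adjusted p = 0.00861; 0.113 with a preset correlation of 0.1). Scaling to total counts left 5 of these markers lower and 3 higher, and moved their median from -0.51 to -0.01, from the authors' deposited table. Among 17 neuronal and synaptic genes, Tubb3, a neuronal tubulin (-2.76 ± 0.28), Rab3a, of synaptic vesicles (-2.08 ± 0.31), Stmn3 and Cadps were among those that fell and Gap43 rose (1.45 ± 0.39) in the authors' deposited table (list test adjusted p = 0.00302; 0.0652 with a preset correlation of 0.1). Of the neuronal genes 5 were lower and 1 higher; scaled to total counts 4 were lower and 2 higher, with the median moved from -0.82 to -0.31, and after removal of the length and GC trends 10 were lower and 1 higher, from the authors' deposited table. Of 16 tested genes of the non-neuroendocrine SCLC list, 13 rose and 0 fell in the authors' deposited table (list test adjusted p = 1.26e-11). The receptor kinase gene Axl (8.96 ± 0.55) and Lgals3 (8.10 ± 0.48), which fibroblasts and macrophages also express, were among those that rose in the authors' deposited table. Among 7 tuft cell markers, Alox5ap, which leukocytes also express (7.61 ± 0.64), Avil (2.93 ± 0.50) and Ltc4s (1.58 ± 0.57) rose in the authors' deposited table (list test adjusted p = 0.0219; 0.0739 with a preset correlation of 0.1).

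In the authors' deposited table antigen presentation genes rose in the same libraries in which all 14 immune cell markers rose. Of 22 MHC class I pathway genes, 15 rose and 0 fell in the authors' deposited table (list test adjusted p = 0.00027), with a median log2 fold change of 1.62, or 1.86 relative to genes with a mean of at least 100. Nlrc5 rose by 4.98 ± 0.63 (adjusted p = 4.61e-14), Tap1 by 2.47 ± 0.36 (adjusted p = 1.36e-10) and H2-D1 by 1.10 ± 0.32 (adjusted p = 0.00318) in the authors' deposited table. H2-K1 had 0.53 ± 0.28 (adjusted p = 0.132) in the authors' deposited table, and 1.04 (adjusted p = 0.00118) when scaled to total counts. All 8 MHC class II genes, known from professional antigen-presenting cells but not confined to them, rose in the authors' deposited table (list test adjusted p = 2.24e-25). Ctss, a lysosomal protease, was at least 14400-fold and H2-Aa at least 6780-fold higher.

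Genes of interferon and inflammatory signalling rose beside these immune markers. Of 29 interferon response genes, 23 rose and Ifi27 fell (-0.73 ± 0.30) in the authors' deposited table (list test adjusted p = 1.27e-11). Gbp2, a guanylate-binding protein, had 10.41 ± 1.55 and Oasl2, an antiviral effector, 7.52 ± 0.69 in the authors' deposited table. Of 21 chemokines and inflammatory cytokines, 18 rose and 0 fell in the authors' deposited table (list test adjusted p = 3.65e-17), with the cytokine gene Il1b at least 8230-fold higher and Cxcl10 at 4.04 ± 0.69 (adjusted p = 4.96e-08). Among 11 nucleic acid sensing genes, Rigi (3.80 ± 0.56), Ifih1, Tlr3, Sting1 (1.84 ± 0.47) and Ikbke rose and Mavs (-0.78 ± 0.28) and Cgas (-1.06 ± 0.34) fell in the authors' deposited table. The sensing list did not pass (list test adjusted p = 0.134). Of 16 immune checkpoint ligands and related surface genes, 10 rose (11 adjusted over the list alone) and Cd276 (-1.32 ± 0.33) and Nectin2 (-1.73 ± 0.30) fell in the authors' deposited table (list test adjusted p = 0.000803). The costimulatory genes Cd86 and Cd80, known from antigen-presenting cells, were at least 226-fold and 6.54 ± 0.70 higher in the authors' deposited table. The NKG2D ligand genes Raet1a, Raet1e (3.38 ± 1.10), Ulbp1 (0.91 ± 0.27) and H60b rose in the authors' deposited table. That list of 4 did not pass (list test adjusted p = 0.0708).

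Genes of the splicing machinery were lower in part, in libraries where short transcripts fell more than long ones. Of 42 core spliceosome components, 25 fell (30 adjusted over the list alone) and Sf3b1 rose (0.65 ± 0.26) in the authors' deposited table (list test adjusted p = 9.04e-08). The median log2 fold change was -0.94, or -0.69 relative to genes with a mean of at least 100, and scaling to total counts left 10 lower, 3 higher and a median of -0.43, from the authors' deposited table. Snrpd2, a core Sm protein, had -2.23 ± 0.45 (adjusted p = 5.36e-06) and Sf3b3, of the U2 particle, -1.61 ± 0.23 (adjusted p = 3.72e-11) in the authors' deposited table. Of 25 hnRNP proteins, 8 fell and Ptbp2 (0.71 ± 0.28) and Ptbp3 (1.33 ± 0.37) rose in the authors' deposited table (list test adjusted p = 0.00162; 0.0739 with a preset correlation of 0.1). The median of the hnRNP genes turned from -0.45 to 0.06 when scaled to total counts, with 5 lower and 3 higher, and after removal of the length and GC trends 13 were lower and 0 higher, from the authors' deposited table. Hnrnpl had -1.47 ± 0.23 in the authors' deposited table. Among 13 SR proteins, Srsf10 (0.64 ± 0.25), Srsf11 (0.75 ± 0.23) and Tra2a (0.76 ± 0.31) rose and Srsf9 fell (-1.58 ± 0.33) in the authors' deposited table, and Srsf1 had -0.19 ± 0.30 (adjusted p = 0.663). The SR protein list did not pass (list test adjusted p = 0.578), and its median turned from -0.05 to 0.19 when centred and to 0.45 when scaled to total counts, from the authors' deposited table. After removal of the length and GC trends 1 SR gene was higher and 3 were lower, with a median of -0.15, from the authors' deposited table.

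Of 26 tissue-restricted splicing regulators, 8 fell and Srrm4 (2.02 ± 0.70), Elavl4 (1.05 ± 0.38), Mbnl1 (1.09 ± 0.35), Mbnl3 and Qki rose in the authors' deposited table. From the authors' deposited table, the median of these regulators turned from -0.45 to 0.05 when scaled to total counts, with 5 lower and 6 higher, and the list did not pass (list test adjusted p = 0.0555; 0.00183 after removal of the length and GC trends). The epithelial splicing genes Esrp2 (-4.30 ± 0.96) and Esrp1 (-3.53 ± 0.96) and the neuronal gene Elavl2 (-7.11 ± 1.15) fell in the authors' deposited table. Of 12 protein arginine methyltransferases and partners, 7 fell (9 adjusted over the list alone) and Prmt8 rose (at least 6.82-fold) in the authors' deposited table (list test adjusted p = 0.000961). Scaled to total counts, the authors' deposited table gave 2 of these 12 as lower and 2 as higher. Prmt1 had -2.30 ± 0.32 (adjusted p = 1.3e-11), Prmt5 -1.28 ± 0.34 (adjusted p = 0.000878) and Carm1 -1.04 ± 0.26 (adjusted p = 0.0004) in the authors' deposited table. The calls of Prmt5 and Carm1 ended when the authors' deposited table was scaled to total counts (-0.77, adjusted p = 0.0601, and -0.53, adjusted p = 0.0956). Among 10 splicing factor kinases, Clk1 (1.69 ± 0.30), Clk4 (1.06 ± 0.26), Prpf4b and Srpk3 rose and Dyrk1b fell (-2.02 ± 0.37) in the authors' deposited table. The splicing kinase list did not pass (list test adjusted p = 0.497). Among 14 nonsense-mediated decay factors, Upf1, the central helicase (-1.31 ± 0.23), Smg5, Smg9, Eif4a3 and Rbm8a fell and Smg1 rose (0.80 ± 0.25) in the authors' deposited table. Upf1 alone of these falls kept its call when scaled to total counts. The list of decay factors did not pass (list test adjusted p = 0.0609; 0.0445 after removal of the length and GC trends).

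Ribosomal protein and cholesterol genes fell throughout their lists. All 24 cytosolic ribosomal protein genes, whose transcripts are short, fell in the authors' deposited table (list test adjusted p = 6.89e-15). The median was -1.48 (-1.24 relative to genes with a mean of at least 100), and Rpl18 had -2.53 ± 0.30 (adjusted p = 3e-15), in the authors' deposited table. After scaling to total counts 18 of them were called lower, and after removal of the length and GC trends 16 were called lower with a median of -0.90, from the authors' deposited table. All 17 cholesterol biosynthesis genes fell in the authors' deposited table (list test adjusted p = 3.5e-11), among them the squalene synthase gene Fdft1 (-2.29 ± 0.30). Of these 17, 14 stayed lower when scaled to total counts, and all 17 after removal of the length and GC trends, from the authors' deposited table.

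Of 21 mitotic genes, 15 fell and Mki67 (0.91 ± 0.26, adjusted p = 0.0016), Cenpf (1.15 ± 0.27) and Cenpe (0.86 ± 0.26) rose in the authors' deposited table (list test adjusted p = 4.16e-05). When scaled to total counts 10 were lower and 3 higher, with the median moved from -1.11 to -0.61, and after removal of the length and GC trends 17 were lower and 0 higher, from the authors' deposited table. The regulators of mitosis Ube2c (-2.21 ± 0.34) and Plk1 (-1.61 ± 0.31) had the largest falls of the list in the authors' deposited table. Of 22 DNA replication genes, 10 fell and 0 rose in the authors' deposited table (list test adjusted p = 4.19e-05), with Gins2 at -1.92 ± 0.30 and Mcm5, of the replicative helicase, at -1.75 ± 0.24. Scaling to total counts left 6 of these 22 lower and moved their median from -0.66 to -0.16, from the authors' deposited table. In the list of 14 tumour suppressor and MYC family genes, Rb1 rose (2.54 ± 0.35, adjusted p = 9.89e-12) and Sox2 (-2.30 ± 0.31), Nfib (-1.11 ± 0.27) and Myc (-1.18 ± 0.29, adjusted p = 0.000308) fell in the authors' deposited table. The calls of Myc (-0.68, adjusted p = 0.0546) and Nfib ended when the authors' deposited table was scaled to total counts. The list did not pass, with a median of 0.16 and a mean of -0.05 in the authors' deposited table and a test that pointed down (list test adjusted p = 0.444). Trp53 had 0.44 ± 0.68 (adjusted p = 0.66), Mycl 0.14 ± 0.49 (adjusted p = 0.863) and Mycn -0.56 ± 0.67 (adjusted p = 0.557), in the authors' deposited table.

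Among 18 p53 targets, Cdkn1a (2.15 ± 0.45, adjusted p = 1.13e-05), Gdf15 (1.93 ± 0.39), Fas, Eda2r and Trp53inp1 rose (8 adjusted over the list alone) and Bbc3 (-1.80 ± 0.37), Bax (-1.80 ± 0.37), Zmat3 and Aen fell in the authors' deposited table. The p53 target list did not pass (list test adjusted p = 0.513). In the BCL2 family of 13, Bcl2 (1.82 ± 0.43), Mcl1 (1.28 ± 0.40), Bcl2a1b and Hrk rose and Bcl2l1 (-1.0 ± 0.29), Bcl2l2, Bid and Bok fell in the authors' deposited table. The BCL2 family did not pass (list test adjusted p = 0.628). Its median was -0.11, its mean 0.65 and the test pointed down, and the median turned to 0.13 when centred and to 0.39 when scaled to total counts, from the authors' deposited table. Among 15 genes of the unfolded protein and integrated stress response, Atf3 (3.75 ± 0.37), Ddit3 and Dnajb9 (2.26 ± 0.32) rose and Asns, Chac1, Ddit4, Psat1 and Phgdh (-2.56 ± 0.28) fell (6 adjusted over the list alone) in the authors' deposited table. The stress response list did not pass (list test adjusted p = 0.3), and its median from the authors' deposited table turned from -0.11 to 0.14 when centred and to 0.40 when scaled to total counts. Of 15 hypoxia and glycolysis genes, 6 rose and Egln3 fell (-1.45 ± 0.58) in the authors' deposited table, with Ndrg1 at 3.04 ± 0.33 and Vegfa at 1.53 ± 0.29. The hypoxia list did not pass (list test adjusted p = 0.147; 0.0329 when scaled to total counts). Among 13 mitochondrially encoded genes, mt-Nd6 rose (0.73 ± 0.28; 0 genes adjusted over the list alone) in the authors' deposited table. The mitochondrial list did not pass (list test adjusted p = 0.598), and its median from the authors' deposited table turned from -0.23 to 0.02 when centred and to 0.28 when scaled to total counts.

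Adjusted over the list alone, 31 of the 37 lists kept the counts given, and the other 6 are named with theirs, from the authors' deposited table. Scaled to total counts, the authors' deposited table gave 11 p53 targets higher and 3 lower, 9 and 0 hypoxia genes, 7 and 0 sensing genes, 6 and 5 stress response genes, and 4 and 1 tumour suppressor and MYC family genes. The same scaling gave 5 genes higher and 1 lower in the BCL2 family and among decay factors, and 5 and 0 mitochondrially encoded genes, from the authors' deposited table. Trend removal gave 2 genes higher and 9 lower among tissue-restricted regulators, 0 and 3 among decay factors, 4 and 1 in the BCL2 family and 5 and 5 in the stress response list, from the authors' deposited table. The medians of the tumour suppressor, BCL2 and stress response lists turned to -0.16, 0.07 and 0.37 with it, from the authors' deposited table. A test of absolute log2 fold changes above 1 left 3161 genes higher and 563 lower from the authors' deposited table. Scaling to total counts also ended the calls of Lpcat1, Ifi27, Mavs, Cgas, Zmat3, Bcl2l1, Bcl2l2, Bid and Egln3 from the authors' deposited table. Removal of the length and GC trends ended those of Pcsk1, Tra2a, Srsf10, Ptbp2, Ptbp3, Clk4, Prpf4b, Smg1, Smg9, Eif4a3, Ulbp1, Mki67, Cenpf, Cenpe, Sf3b1, Elavl4, Mbnl1, Qki, Lpcat1, Ifi27, Mavs, Trp53inp1, Bax, Bcl2l1, Bcl2l2, Bok and Egln3 from the authors' deposited table. No level in SCLC cells could be separated from one in other cells of the same library. This limit holds for the falls of the neuroendocrine, neuronal, splicing, mitotic and DNA replication lists as well as for the rises.

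**Figure D2:**
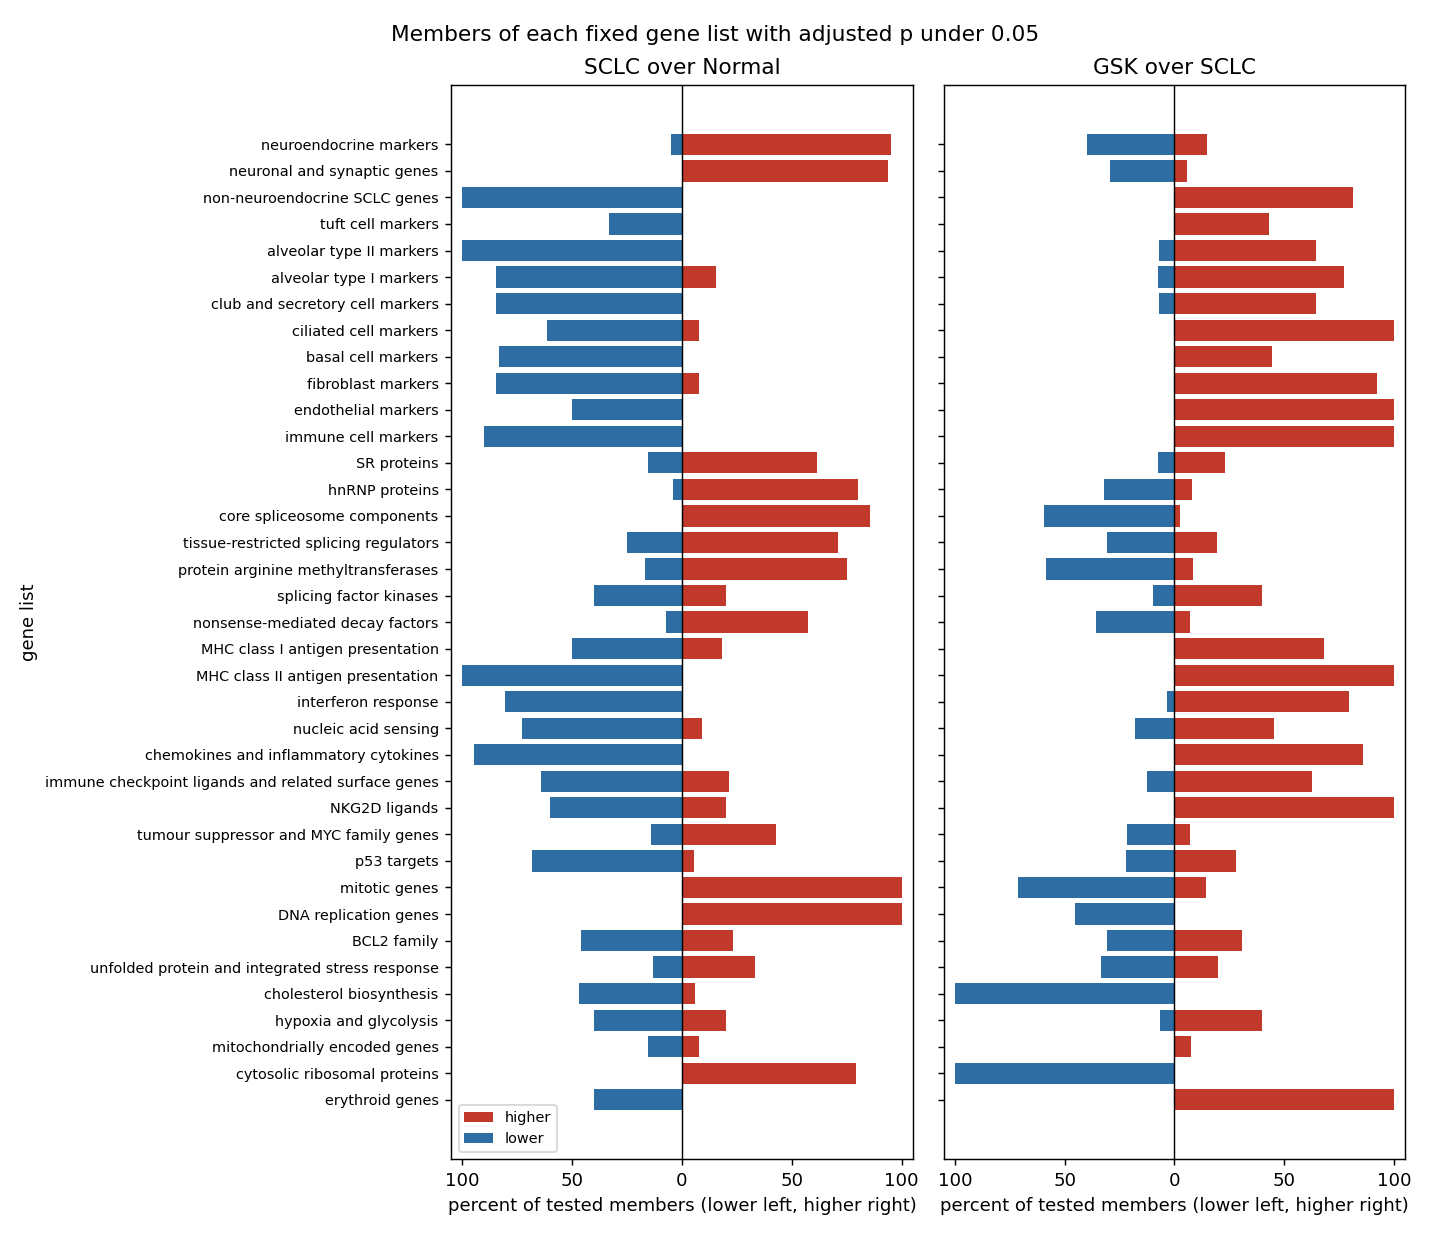
The percent of tested members of each of the 37 lists called higher (to the right) and lower (to the left) in the authors' deposited tables, for SCLC over Normal and for GSK over SCLC, with the authors' scaling. In the authors' deposited table all 14 immune cell markers were higher and all 24 cytosolic ribosomal protein genes were lower in GSK, of which 18 stayed lower, and the medians of the SR, hnRNP, tissue-restricted splicing, BCL2, stress response and mitochondrial lists turned positive, when scaled to total counts.

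Both comparisons together asked whether genes that differed between tumour and normal organoids moved back in GSK. Of 23797 genes tested in both, 2612 were higher in SCLC than in Normal and then lower in GSK, and 2575 were lower and then higher, in the authors' deposited tables. A further 478 rose in both comparisons and 388 fell in both, so 85.7% of the genes changed in both went opposite ways in the authors' deposited tables. Cd274, B2m, Tap1, Rb1, Cdkn1a, Sftpc and Scgb1a1 fell and then rose, and Insm1, Myc, Prmt1, Prmt5 and Carm1 rose and then fell, in the authors' deposited tables. The falls of Myc, Prmt5 and Carm1 in GSK were no longer called when the authors' deposited table was scaled to total counts. Neurod1 and Mki67 rose in both, and the second call of Mki67 ended after removal of the length and GC trends. Independent lists of the same sizes would give 1155, 1160, 1257 and 1066 genes in the 4 classes.

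The SCLC libraries served in both comparisons, which makes opposite signs common by chance. Across genes, which are not independent replicates, the log2 fold changes had a correlation of -0.61 and a covariance of -4.9 in the authors' deposited tables, against -0.35 and -0.33 in simulated groups with no true change. Signs were opposite for 67.9% of the genes in the authors' deposited tables, against 63.3% in those groups. The simulated values rest on an assumed share of the error for the SCLC libraries, set alike for all genes. For genes with few counts in SCLC the share may be larger, which would make opposite signs without true change more common. Other shares were not tested, so the simulated correlation and signs do not decide how much of the observed ones the shared libraries explain. No value without true change was obtained for the 85.7%, part of which can come from the shared SCLC libraries. Without the marker lists of other cell types and genes under the floor in SCLC, 4450 genes went opposite ways and 860 the same way, from the authors' deposited tables. Only listed markers and genes under the floor were left out, so other transcripts of these cell types stayed in. These counts therefore do not separate a difference in cell types between the groups from a change within SCLC cells.

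**Figure D3:**
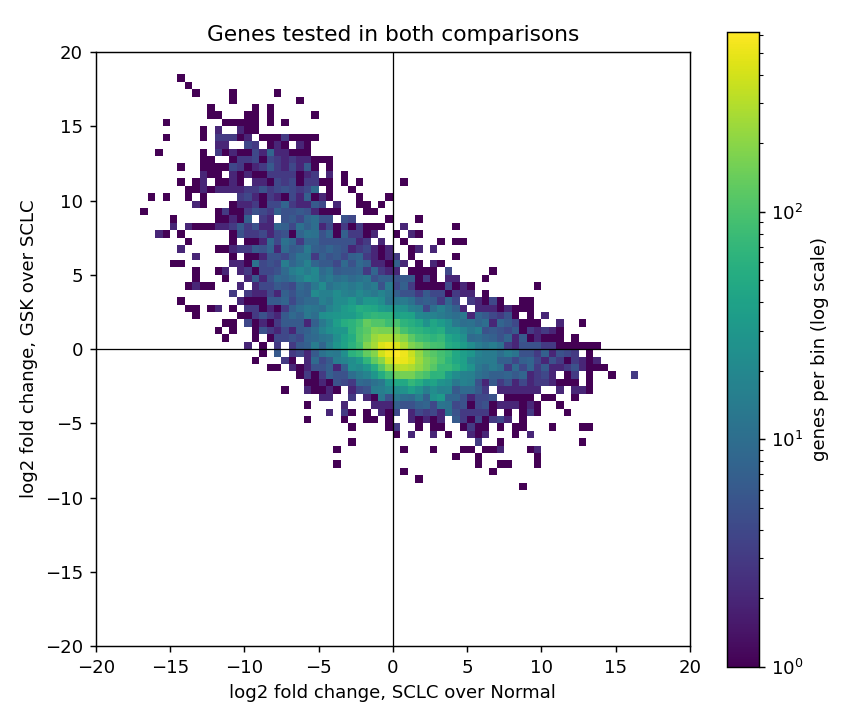
Number of genes (log colour scale) in bins of 0.5 log2 units of the fold change of SCLC over Normal (horizontal axis) and of GSK over SCLC (vertical axis), for 23797 genes tested in both of the authors' deposited tables. In the upper left and lower right areas lie 5187 genes that passed both tests in the authors' deposited tables, and in the other areas 866.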

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

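Tests chosen only after the result was seen were the check for an exchange of GSK and Normal libraries, both readings of the MHC class I and interferon rise, the test of dilution, the reading of the list tests left after removal of the length trend, and the reading of scaling by list.

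Rn18s, the 18S ribosomal RNA, drew attention as a signal in values that no comparison used, because the authors' deposited tables list it with a fold change and no p-value. Its log2 fold change was 4.83 for SCLC over Normal and -5.13 for GSK over SCLC in the authors' deposited tables. It made up 0.0761% of the implied total in Normal, 2.3% in SCLC and 0.0912% in GSK, from the authors' deposited tables. By the DESeq2 rules for missing values, a fold change without a p-value marks a gene with an outlying count in a library. These fold changes and shares may therefore rest on few libraries. Rn18s lacked a p-value in both comparisons, and only the SCLC libraries serve in both. The outlying count may thus lie in an SCLC library, but no single library was seen.

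Markers of other cell types rose in GSK together: all 14 immune, all 10 endothelial, 12 of 13 fibroblast and all 5 erythroid genes, of which 4, 7, 11 and 1 lay above the floor in SCLC, 0 of them members of another list. Induction in the SCLC cells as the whole cause is argued against by variable segments of immunoglobulin and T-cell receptor genes, which only lymphocytes join. Of 362 annotated segments, 180 rose in the authors' deposited table, 99.4% of them from an SCLC mean under the floor. These were 74.4% of the 242 segments with an adjusted p, of which 0 fell. That share and the 0 carry little weight, since segments under the floor in SCLC get an adjusted p mainly through their GSK level. Counts per gene do not show whether the segments were joined, so the rises argue against induction only if these transcripts came from lymphocytes. An exchange of GSK with Normal libraries is argued against by Xist, with a mean of 31710 in Normal and 1.76 in SCLC. Its implied level in GSK lay 10.98 log2 units under Normal, on the side of SCLC, as for organoids that came from SCLC. The gap was set across tables that were scaled separately, and its size alone would be the same after an exchange. Cells of other types in the GSK libraries are a candidate explanation, as a hypothesis, with Lyz2 (94202), S100a9 (13346), Cdh5 (5311) and Hba-a1 (2492) among their most abundant transcripts in GSK by the authors' deposited table. Whether such cells came with the treatment or with another difference in how these organoids were grown or collected stays open, since no sort, gate or growth condition is given in the sources used here.

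The MHC class I list (median log2 fold change 1.62) and the interferon response list (median 4.0) rose in GSK while all 14 immune cell markers rose, in the authors' deposited table. Transcripts brought by other cell types and a response of the SCLC cells to GSK cannot be told apart for these lists, because each is confounded with the group and no value is tied to a cell type. Genes such as B2m and Cd274 are expressed by immune and endothelial cells and may equally be induced in tumour cells. No table held a value that excludes either reading.

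In the core spliceosome, ribosomal protein and cholesterol lists, 66 of 83 tested genes fell in GSK, with a pooled median of -1.28, in the authors' deposited table. GC content as the whole cause is argued against, since removal of its trend took away -2.8% of the distance to other genes. Transcript length as the whole cause stays open, since its removal took away 34.1%, between the bounds set before. All 3 lists stayed lower after joint removal (list test adjusted p = 3.22e-07, 1.49e-08 and 2.55e-12). That does not decide on length, since the longest transcript stood for each gene and the length trend may be removed only in part. In the ribosomal protein and cholesterol lists, 78.0% of the genes that fell (32 of 41) stayed lower after scaling to total counts. The upper quartile of their members was then -0.78. These values argue against the shift of 0.51 as the whole cause, by a reading set after the shares were seen. A larger shift was not tested and stays open, and length and scaling may account for part of the fall. For the core spliceosome scaling to total counts stays open as the whole cause, since 40.0% (10 of 25) stayed lower with an upper quartile of 0.02. Over all 3 lists 63.6% (42 of 66) did, between the bounds set before. Dilution of the SCLC cells stays open, because the only reference, 139 genes restricted to SCLC, is no clean measure of it (16 of them rose), so that the distance of the pooled median from theirs (-0.38, which is over 2 bootstrap standard errors of 0.17 over genes) does not decide, and a response of the SCLC cells to GSK was not tested apart from it.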

How the results depend on the processing

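Chosen only after the result was seen were the tests with centring, a minimum mean of 10, a Wald test of changes above 1, a preset correlation of 0.1, ranks, removal of length and GC trends, and opposite change without markers of other cell types or scaled to total counts. No passing list test changed direction, while the median of the hnRNP list, lower in GSK, turned from -0.45 to 0.06 when scaled to total counts, from the authors' deposited table. Among the called genes meant below only Prpf4b in SCLC against Normal changed sign (-0.49, adjusted p = 0.0394), to 0.0 and no call after removal of length and GC trends, from the authors' deposited table. The Wald test of absolute log2 fold changes above 1 left 6340 genes in SCLC against Normal (2949 higher, 3391 lower) and 3724 in GSK against SCLC (3161 higher, 563 lower), from the authors' deposited tables; it asks for a larger change by construction. Scaling to total counts left 1970 genes lower in GSK, against 4404, because it adds 0.51 to each log2 fold change. All other counts of genes and lists stayed within 1.5 times those given. Lists passing higher and lower in SCLC against Normal numbered 9 and 12, and from 6 to 12 and from 10 to 15 under the alternatives. In GSK against SCLC they numbered 16 and 9, and from 14 to 17 and from 6 to 11. Opposite change (5187 genes) ranged from 4023 to 4650 genes.

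The genes meant here are those of the naming rule, those behind counts of 5 or fewer, and Xist, the Y-linked genes, Actb and Gapdh. In GSK against SCLC scaling to total counts ended 18 calls (Prmt5, Carm1, Myc, Nfib, Rbm8a, Smg5, Smg9, Eif4a3, Gapdh, Lpcat1, Ifi27, Mavs, Cgas, Zmat3, Bcl2l1, Bcl2l2, Bid and Egln3) and added H2-K1. Centring ended 7 (Lpcat1, Smg5, Ifi27, Mavs, Zmat3, Bcl2l2 and Egln3) and added H2-K1, and leaving out the filter ended those of Ifi27 and Bcl2l2. Removal of length and GC trends ended 28 (Pcsk1, Tra2a, Srsf10, Ptbp2, Ptbp3, Clk4, Prpf4b, Smg1, Smg9, Eif4a3, Ulbp1, Mki67, Cenpf, Cenpe, Sf3b1, Elavl4, Mbnl1, Qki, Uty, Lpcat1, Ifi27, Mavs, Trp53inp1, Bax, Bcl2l1, Bcl2l2, Bok and Egln3) and added H2-K1 and Srsf1. In SCLC against Normal scaling to total counts ended 3 calls (H2-K1, Srsf11 and Prpf4b), centring 6 (Gapdh, Dyrk1a, Psmb9, Icosl, Bak1 and Pdk1) and no filter 3 (Tek, Prpf4b and Icosl). Removal of the trends ended, beside Prpf4b, 5 calls there (Srpk2, Srsf11, Ptbp3, Psmb9 and Bak1). It brought the list of ciliated cell markers (adjusted p = 0.0439), of SR proteins (0.0257) and of tumour suppressor and MYC family genes (0.0336) past the threshold in SCLC against Normal. The Wald test above 1 ended 64 calls of these genes in SCLC against Normal and 93 in GSK against SCLC. The cause of these changes was not tested beyond the shift that each setting makes.

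No paired analysis was possible because the labels give the groups the same replicate numbers but no value of a single library was used. For the same reason other size factors, another test on counts, leaving out each replicate, a joint fit of the 9 libraries, another pseudocount, an estimated correlation, other splits of the libraries and the structure of the samples were not run, and the alternative of taking the authors' adjusted p is the test used throughout. Counts could not be repeated without the GSK libraries that hold markers of other cell types, since all 3 enter one fold change. At the p-value cut of the calls and with the authors' standard errors, a true change of 1 log2 unit is expected to pass in 44.7% of the genes tested in SCLC against Normal and in 37.6% in GSK against SCLC, and one of 2 units in 66.9% and 62.7%, from the authors' deposited tables.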

Other observations

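All gene families and tests here were chosen only after the values were seen. Of the families of gene names examined outside the fixed lists, some moved in opposite directions in the 2 comparisons, which share the SCLC libraries, and others did not; no test was made over families. Of the protocadherin genes tested, 27 rose and 9 fell in SCLC, and 14 rose and 8 fell in GSK (21 and 3 when scaled to total counts, 12 and 9 after removal of the length and GC trends), in the authors' deposited tables. Of the potassium channel genes tested, 40 rose and 15 fell in SCLC, and 25 rose and 15 fell in GSK (31 and 10 when scaled, 28 and 17 after trend removal), in the authors' deposited tables. Of the zinc finger genes of the Zfp series tested, 81 rose and 103 fell in SCLC (89 and 84 after trend removal), and 77 rose and 77 fell in GSK (120 and 28 when scaled, 52 and 93 after trend removal), in the authors' deposited tables. Of 53 replication-dependent histone genes, which package new DNA, 47 rose in SCLC and 22 fell in GSK (11 when scaled to total counts), in the authors' deposited tables. Of 77 mitochondrial ribosomal protein genes, 62 rose and 2 fell in SCLC, and 50 fell in GSK (21 lower and 1 higher when scaled to total counts), in the authors' deposited tables. Of 36 genes of respiratory complex I, 24 rose in SCLC and 30 fell in GSK (16 lower and 1 higher when scaled to total counts), in the authors' deposited tables. Of 39 proteasome genes tested in GSK against SCLC, 27 fell and 3 rose (10 lower and 4 higher when scaled to total counts), in the authors' deposited table. After removal of the length and GC trends, 9 histone, 35 mitochondrial ribosomal protein, 13 complex I and 18 proteasome genes were lower in GSK, and 0, 1, 0 and 4 higher, from the authors' deposited table. In SCLC against Normal the same removal left 38 histone, 58 mitochondrial ribosomal protein and 14 complex I genes higher, and 0, 3 and 1 lower.

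Hox genes, which set position along the body axis, fell in SCLC (12 of 18 tested) and rose in GSK (10 of 12 tested), with the same counts when scaled to total counts, in the authors' deposited tables. Of 39 collagen genes, 23 fell and 8 rose in SCLC (23 and 9 when scaled to total counts), and of 41, 27 rose and 2 fell in GSK (32 and 1 when scaled), in the authors' deposited tables. Of 55 cytokine and chemokine receptor genes tested in GSK against SCLC, 48 rose and 1 fell (52 and 1 when scaled to total counts), among them the neutrophil receptor gene Cxcr2 and the monocyte receptor gene Ccr2, in the authors' deposited table. Of 31 integrin genes, 16 fell and 5 rose in SCLC, and 19 rose and 0 fell in GSK (24 and 0 when scaled), in the authors' deposited tables.

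The Y-linked genes Ddx3y (1.83 ± 0.36), Eif2s3y (1.33 ± 0.28), Kdm5d (1.32 ± 0.23) and Uty (1.06 ± 0.30) rose in GSK against SCLC in the authors' deposited table. Actb, a common reference gene, had -0.98 ± 0.27 in SCLC over Normal and 0.23 ± 0.32 in GSK over SCLC, and Gapdh had 0.80 ± 0.31 and -1.18 ± 0.35, in the authors' deposited tables. In SCLC against Normal 19 genes with a mean of at least 1000 had a fold change without a p-value, and 18 in GSK against SCLC, among them Rn18s, mt-Rnr1 and mt-Rnr2 in both of the authors' deposited tables.

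The 139 genes under the floor in Normal with an SCLC mean of at least 300 had a median log2 fold change of -0.91 in GSK (quartiles -1.85 and 0.03), in the authors' deposited table. Of these, 63 fell and 16 rose, and their SD of 1.97 was 4.93 times their median standard error of 0.4. A plain dilution of SCLC cells would move them alike, but other cell types can express some of them, so this spread does not decide on dilution. It had first been read as excluding dilution and was set aside as a test after its value was known.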
